A study of Homo sapiens with 33 samples.

How the data were processed

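The data were intensity values of single-colour HG-U133A 2.0 arrays, which measure RNA by hybridization to sets of short probes. The intensity values had been made by the authors before they were deposited. Per the submitters' processing notes the arrays were processed with GCOS 1.4, the array maker's software. The algorithm, the scaling target and any filter are not given in the sources used here, and no detection calls were used. Per the labels, 2 µg of total RNA was extracted with RNeasy columns from cells kept in RPMI medium with fetal calf serum, and the replicates were biological. What the replicate numbers S1 to S6 stand for is not given in the sources used here.

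The deposited intensities were linear signals from 0.136 to 87680 and had been scaled between arrays, as their values show. The mean after trimming 2% of probe sets at each end was 1000.3 to 1000.4 on every array, and array medians lay within a factor of 1.29. They were therefore not normalized again, a rule fixed in advance. Scaling to a common mean can shift all other genes of an array when many strong signals rise or fall, so the median log2 fold change over all genes is given where it was above 0.1 or below -0.1. The values used were log2(signal + 16). The pseudocount of 16 makes fold changes of low signals smaller. No pair of arrays held the same values, and all 33 arrays were used. Correlation of an array with the others of its group was 0.9422 to 0.9727.

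The arrays held 22277 probe sets. The 62 control probe sets were left out of the tests, as were 52 probe sets for transcripts that mark sex. Other genes on chromosome X, such as FOXP3, were kept. A probe set was kept if it was above the 40th percentile of its array on at least 3 of the 33 arrays, which left 15553. That percentile was 106 to 144 signal units, and signals under it cannot be separated from background here. For a named gene under it on all 3 arrays of a group the fitted log2 fold change is not exact. Between 2 groups the results give a bound instead, as the mean log2 value of the brighter group minus that of the dimmer group with each dimmer signal raised to the percentile of its array, and no fold change where both groups lay under it. Where the dependence on the processing or a flagged result needs the fitted value of such a gene, it is not exact. These bounds were chosen after the results were seen. Such genes are kept in the list medians at their measured signals. Among called genes given with a fold change between groups, 2 of 3 arrays of a group lay under it for HK3 (untreated, 24 h), MMP1 and MMP10 (untreated, 24 h), MMP1 and TKTL1 (hATG, 24 h) and IL10 (untreated and hATG 10 µg/mL, 6 h), and 1 of 3 for MET, MCM4, TNFRSF4, CCL7, IL2RA, LEP, CD244 and VIPR1. Probe sets were assigned to genes by the platform annotation and its Entrez identifiers. A single symbol was given for 19070 probe sets, of which 19058 matched a current gene by identifier and 12 did not. The 1043 probe sets with several symbols and the 2108 with no symbol, controls aside, were not used. The probe set with the highest mean stood for a gene that had several, as 3112 genes did. In all 8791 genes were tested, named by the symbols of the annotation.

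Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a trend). A single model with 11 group means was fitted to the 33 arrays, so that all groups shared an estimate of the spread, with no replicate block. Tests were two-sided, p values were adjusted by the Benjamini-Hochberg method over the genes of each of the 19 comparisons, and a gene was called at an adjusted p under 0.05. An exact permutation test of 3 arrays against 3 cannot give a p under 0.1. Groups were compared only within the same replicate numbers, S1 to S3 or S4 to S6, because 10 µg/mL and the other doses were in separate sets. An effect of 10 µg/mL and one of 2.5 or 40 µg/mL were therefore only set side by side. Differences over time, over dose and between antibodies over time or dose were tested as differences of differences in the same model. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

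In all, 22 gene lists were tested with limma's camera at its preset correlation between genes of 0.01, adjusted over the lists of a comparison by the Benjamini-Hochberg method. They were T cell identity, T cell activation, Regulatory T cell, T helper cytokines, NK and cytotoxic, B cell, Monocyte, Dendritic cell, Neutrophil, Platelet, Erythroid, Type I interferon response, Interferon gamma response, Chemokines and inflammatory cytokines, NF-kappaB targets, Apoptosis and p53 targets, Proliferation, Complement and Fc receptors, MHC class II, Immediate early and heat shock, Glycolysis and Reference genes. They held 8 to 26 measured genes, and some genes stood in more than 1 list. Each list was also tested with a correlation estimated from the arrays. The members of each list were also adjusted over the list alone.

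The text named genes by a rule. For comparisons of an antibody with untreated cells or of rATG with hATG it took the 10 highest and the 10 lowest log2 fold changes among called genes with the same sign in all 3 same-numbered pairs, and 5 and 5 for other comparisons. It added up to 4 called members of each list with the largest absolute log2 fold change, and 18 genes in every comparison of 10 µg/mL, called or not. Of these, the text gives those whose calls held best across the alternatives and those that characterise a list. That selection was made after their values were seen.

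Whether equal replicate numbers pair arrays was tested on residuals from the group means. For all 33 arrays the mean residual correlation was highest with arrays of the same number. In 15 of the 19 comparisons every same-numbered pair had a residual correlation above 0.1. In the other comparisons, hATG at 10 µg/mL against untreated cells at 6 h, rATG against hATG at 10 µg/mL and 6 h, and both changes over time that involve hATG, the lowest was 0.08, 0.084, -0.018 and 0.084. The value with the replicate number as a block is given beside a result where every same-numbered pair was above 0.1 and the block changed a call or moved a count by over 1.5 times.

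The alternatives were no filter, a filter at the 60th percentile, pseudocounts of 1 and 64, quantile normalization, centring each array on its median, the median of a gene's probe sets, all probe sets, the replicate number as a fixed or a random block, array weights, no trend, an added threshold of 1 on the absolute log2 fold change, a fit of only the groups compared, and leaving out each array in turn. For the lists they were an estimated correlation, fry with and without the block, camera with the block, and quantile normalization. The groups, comparisons, tests, lists, rule for named genes and these alternatives were fixed before the data were examined. Leaving out hATG 10 µg/mL 6 h replicate 1 together with the block was added after seeing the data.

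The model was tested on simulated data with the spread of these arrays, 200 changed genes of 8791 and 3 draws. For rATG against untreated cells at 24 h it recovered 22.9%, 60.7% and 85.4% of genes changed by 0.5, 1 and 2 log2 units, and 5.07% of its calls were false. Over the 19 comparisons 2.28% to 7.99% of calls were false, the highest for rATG at 40 µg/mL. For the rATG effect over time it recovered 7.96%, 34.8% and 74.7%, and 6.4% of its calls were false. In simulated lists, a shift of 0.5 in the Monocyte list was recovered and 0 other lists were called. The simulated genes were drawn independently of one another. The simulation therefore says nothing about false calls of lists whose genes are correlated.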

Results

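Gene expression was measured on 33 single-colour arrays in human peripheral blood mononuclear cells (PBMC, the lymphocytes and monocytes of blood) from healthy controls. The cells were cultured without antibody, with rabbit anti-thymocyte globulin (rATG) or with horse anti-thymocyte globulin (hATG), polyclonal antibody preparations raised against human thymus cells and used as immunosuppressants. Each of the 11 groups held 3 arrays. In 1 set of arrays (replicates S1 to S3) untreated cells, hATG at 10 µg/mL and rATG at 10 µg/mL were each measured at 6 h and at 24 h. In the other set (S4 to S6) untreated cells, hATG at 2.5 and 40 µg/mL and rATG at 2.5 and 40 µg/mL were measured at 6 h. Array medians ranged from 203.3 to 262.2 signal units, and 8791 genes were tested. The ratio of the 3 prime to the 5 prime signal of ACTB, a sign of RNA quality, differed between groups, and no comparison was adjusted for it. At 24 h it was 1.34 ± 0.0173 untreated, 1.17 ± 0.0361 with hATG and 1.14 ± 0.0473 with rATG. At 6 h in S1 to S3 it was 1.24 ± 0.03 untreated, 1.36 ± 0.263 with hATG and 1.07 ± 0.0231 with rATG. In S4 to S6 it was 1.26 ± 0.0361 untreated, 1.17 ± 0.0208 and 1.14 ± 0.0361 with hATG at 2.5 and 40 µg/mL, and 1.11 ± 0.0458 and 1.05 ± 0.0805 with rATG at those doses. The mean ratio for GAPDH differed less. At 24 h it was 1.03 untreated, 1 with hATG and 0.971 with rATG. At 6 h in S1 to S3 it was 1.07, 1.18 and 1.05 in the same order. In S4 to S6 it was 1.11 untreated, 1.13 and 1.05 with hATG at 2.5 and 40 µg/mL, and 1.08 and 1.05 with rATG. The number of arrays limits the precision. Values after ± are standard errors of a log2 fold change (3 arrays in each group) or, for signals, standard deviations (n = 3). Each gene said to have risen or fallen moved the same way in all 3 same-numbered pairs of arrays unless stated. Its call also held in every alternative run, each left-out array included, unless another value is given, and apart from the alternative that also asked for a log2 fold change of at least 1. Pairs of counts adjusted over the list alone are given higher first, lower second. Changes written as at least a value are lower bounds on the log2 scale, for genes under the 40th percentile of the array on all 3 arrays of the dimmer group, whose signals were raised to that percentile. Each bound holds for the probe set that stood for the gene, and another probe set of the gene can give less. A list median is a median log2 fold change over its measured genes. Gene positions are on the human assembly GRCh38.p14, and p values are two-sided.

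**Figure D1:**
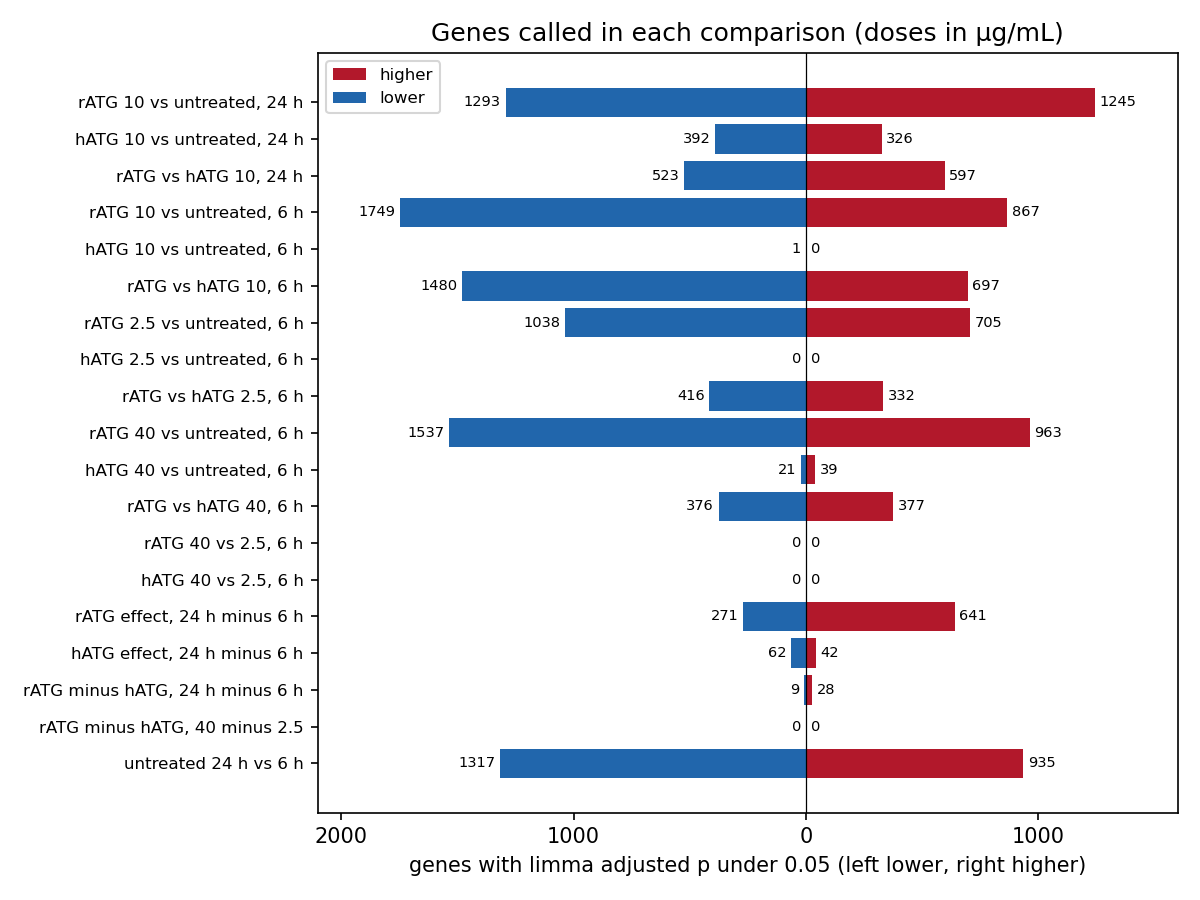
Number of genes that passed an adjusted p of 0.05 (limma) in each of the 19 comparisons, with genes higher to the right and genes lower to the left of 0. rATG against untreated cells gave 1743 to 2616 genes and hATG gave 0 to 718.

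The first question was what 24 h with rATG at 10 µg/mL did to the cells. TNFRSF9, the co-stimulatory receptor 4-1BB, rose by 4.15 ± 0.60 on the log2 scale and TNFRSF4, the co-stimulatory receptor OX40, by 3.23 ± 0.59. IL2RA, the alpha chain of the interleukin 2 receptor (chromosome 10, 6010689 to 6062367), rose by 2.45 ± 0.45, and the inhibitory receptors LAG3 and CTLA4 by 2.49 ± 0.46 and 1.98 ± 0.37. MMP1 and MMP10, neighbours on chromosome 11 (102789919 to 102798160 and 102770502 to 102780628) that encode matrix metalloproteinases, rose by 5.94 ± 1.39 and 5.79 ± 0.70, with 2 of the 3 untreated signals of each under the 40th percentile of their arrays. ZBED2, a zinc finger transcription factor, rose by at least 3.96 to a signal of 2180 ± 299. IL1R2, the decoy receptor of interleukin 1, rose by 3.61 ± 0.39, and of the pantetheinase genes VNN1 fell by at least 4.10 and VNN2 fell too (-3.34 ± 0.33).

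In the rATG group at 24 h, 17 of the 25 measured genes of the T cell activation list rose, 0 fell and 8 did not pass (19 and 0 adjusted over the list alone). EGR3, an early growth response factor, was among those that rose, at 2.86 ± 0.48. The list passed (camera, adjusted p = 4.61e-10, and adjusted p = 0.285 with an estimated correlation). In the Type I interferon response list 11 of 26 measured genes rose, 0 fell and 15 did not pass (13 and 0 adjusted over the list alone), among them IFI6 at 1.98 ± 0.34 and IFI35 at 1.41 ± 0.37. Its median was 0.91 (camera, adjusted p = 0.000441, and adjusted p = 0.588 with an estimated correlation). The Immediate early and heat shock list had 8 of its 13 measured genes higher, 1 lower and 4 not passing (8 and 1 adjusted over the list alone). The chaperone genes HSPE1, HSPH1 and HSP90AA1 gave 1.47 ± 0.17, 1.37 ± 0.27 and 0.91 ± 0.12, while ATF3, a stress response factor, fell (-1.17 ± 0.31). The median was 0.70 (camera, adjusted p = 0.00214, and adjusted p = 0.254 with an estimated correlation). Of 25 measured genes of the Proliferation list, 6 rose, 0 fell and 19 did not pass (6 and 0 adjusted over the list alone), with the replication genes MCM4, MCM2 and PCNA at 1.66 ± 0.22, 1.56 ± 0.26 and 0.95 ± 0.13. Its median was 0.29 (camera, adjusted p = 0.0312, and adjusted p = 0.588 with an estimated correlation). In untreated cells MCM4, PCNA and HSPH1 were lower at 24 h than at 6 h, so their rises are against untreated levels that had fallen. In the Monocyte list 7 of 21 measured genes rose, 2 fell and 12 did not pass (8 and 2 adjusted over the list alone), with SERPINA1, ITGAM and S100A9 at 1.69 ± 0.24, 1.48 ± 0.22 and 1.48 ± 0.30 (camera, adjusted p = 0.156). Of T cell genes, CD27 and CD7 rose (1.57 ± 0.29 and 1.11 ± 0.12) and IL7R, the interleukin 7 receptor, fell (-1.35 ± 0.25). In total 2538 genes passed (limma), 1245 higher and 1293 lower.

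With hATG at 10 µg/mL for 24 h, CST3, which encodes cystatin C, rose by 1.20 ± 0.15 and ITGAM, the integrin CD11b, by 1.18 ± 0.22. CD74, the invariant chain of MHC class II, and HLA-DMA, which loads peptide on class II, rose by 0.83 ± 0.12 and 0.92 ± 0.19. The hexokinase gene HK3 rose by 2.98 ± 0.35 and IL1R2 by 2.03 ± 0.39, whereas CREM, the cAMP responsive element modulator, fell (-1.77 ± 0.21), as did MET, the hepatocyte growth factor receptor (-2.36 ± 0.44), and TKTL1, a transketolase-like gene (-3.57 ± 0.62). The MHC class II list had 5 of its 12 measured genes higher, 0 lower and 7 not passing (7 and 0 adjusted over the list alone). The median was 0.68 (camera, adjusted p = 5.6e-06, and adjusted p = 0.00535 with an estimated correlation). Of 21 measured genes of the Monocyte list, 9 rose, 0 fell and 12 did not pass (10 and 0 adjusted over the list alone). Its median was 0.58 (camera, adjusted p = 1.15e-05, and adjusted p = 0.411 with an estimated correlation). Of the T cell activation list 1 of 25 genes rose and 1 fell (1 and 1 adjusted over the list alone), and the list did not pass (camera, adjusted p = 0.499). IL2RA had 0.99 ± 0.45, adjusted p = 0.18, and adjusted p = 0.0081 with the replicate block (range over the alternatives 0.0081 to 0.439). In total 718 genes passed, 326 higher and 392 lower, and 1430 passed with the replicate number as a block. Centring each array on its median gave 175 higher and 646 lower. The count was 346 when only the groups compared were fitted, 456 without untreated 24 h replicate 1 and 367 without hATG 24 h replicate 1.

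The direct comparison of the antibodies at 10 µg/mL and 24 h asked where their effects differed. MMP1, MMP10 and ZBED2 were higher with rATG than with hATG (6.19 ± 1.39, at least 4.30 and at least 3.86), as were the growth regulator MYC (2.39 ± 0.23) and the nuclear receptors NR4A2 and NR4A3 (2.31 ± 0.33 and 2.19 ± 0.25). FCN1 and CD36, a ficolin and a scavenger receptor of monocytes, were lower with rATG (-1.21 ± 0.19 and -1.66 ± 0.32), as were the aldehyde dehydrogenase gene ALDH2 (-1.85 ± 0.26) and HLA-DMB, an MHC class II chaperone (-1.07 ± 0.23). Of the 25 T cell activation genes 15 were higher with rATG and 0 lower (16 and 0 adjusted over the list alone). The median was 1.25 (camera, adjusted p = 5.88e-14, and adjusted p = 0.109 with an estimated correlation). In the Immediate early and heat shock list 6 of 13 genes were higher and 0 lower (6 and 0 adjusted over the list alone), among them HSPE1 and HSPD1, the mitochondrial chaperonin pair, at 1.28 ± 0.17 and 0.88 ± 0.14. Its median was 0.44 (camera, adjusted p = 1.19e-05, and adjusted p = 0.0258 with an estimated correlation). For MHC class II 2 of 12 genes were lower and 0 higher (0 and 3 adjusted over the list alone). The median was -0.48 (camera, adjusted p = 0.0117, and adjusted p = 0.149 with an estimated correlation). In total 1120 genes differed, 597 higher and 523 lower with rATG, and 1848 with the replicate block. Centring each array on its median gave 690 higher and 321 lower, and the count was 718 without hATG 24 h replicate 1 and 656 without hATG 24 h replicate 3.

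With rATG at 10 µg/mL for 6 h, CXCL11, CXCL9 and CXCL10, chemokines induced by interferon gamma whose genes lie between 76001275 and 76036070 on chromosome 4, rose by at least 6.23, at least 6.14 and 5.99 ± 1.27, and IDO1, a tryptophan-degrading enzyme under the same control, rose by 4.51 ± 0.99. The monocyte-attracting chemokines CCL2 and CCL7 rose by 4.80 ± 0.95 and 5.13 ± 0.83, and INHBA, a subunit of activin, by at least 4.27. TNFRSF9, the lymphotactin gene XCL1 and IL2RA rose by 4.40 ± 0.60, 3.46 ± 0.56 and 2.66 ± 0.45, and the cytokine genes TNF and IL10 by 3.08 ± 0.65 and 2.72 ± 0.53. The leptin gene LEP and VNN1 fell by at least 2.54 and at least 3.34, and the adhesion molecule PECAM1 fell too (-2.79 ± 0.50).

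After 6 h with rATG at 10 µg/mL 11 of the 22 lists passed. In the T cell activation list 24 of 25 measured genes rose, 0 fell and 1 did not pass (24 and 0 adjusted over the list alone). Its median was 2.00 (camera, adjusted p = 7.59e-22, and adjusted p = 0.0402 with an estimated correlation). The Interferon gamma response list had 14 of its 15 measured genes higher, 0 lower and 1 not passing (14 and 0 adjusted over the list alone). The median was 2.85 (camera, adjusted p = 2.66e-12, and adjusted p = 0.0995 with an estimated correlation). Of 12 measured genes of the T helper cytokines list, 10 rose, 0 fell and 2 did not pass (10 and 0 adjusted over the list alone). Its median was 1.80 (camera, adjusted p = 4.49e-08, and adjusted p = 0.0873 with an estimated correlation). In the Chemokines and inflammatory cytokines list 11 of 23 measured genes rose, 0 fell and 12 did not pass (15 and 0 adjusted over the list alone), with CCL20 at 3.78 ± 0.88. The median was 1.98 (camera, adjusted p = 5.45e-09, and adjusted p = 0.0995 with an estimated correlation). The NF-kappaB targets list had 9 of its 14 measured genes higher, 0 lower and 5 not passing (11 and 0 adjusted over the list alone), with ICAM1 and BCL2A1 at 1.97 ± 0.43 and 1.96 ± 0.31. Its median was 1.02 (camera, adjusted p = 3.31e-08, and adjusted p = 0.0995 with an estimated correlation). Of 26 measured genes of the Type I interferon response list, 10 rose, 0 fell and 16 did not pass (13 and 0 adjusted over the list alone), with RSAD2, the antiviral protein viperin, at 4.01 ± 0.81. The median was 0.79 (camera, adjusted p = 3.91e-07, and adjusted p = 0.272 with an estimated correlation). In the Apoptosis and p53 targets list 9 of 17 measured genes rose, 2 fell and 6 did not pass (9 and 3 adjusted over the list alone), with GADD45A and CDKN1A, growth arrest genes, at 1.90 ± 0.21 and 2.03 ± 0.45. Its median was 0.63 (camera, adjusted p = 0.00031, and adjusted p = 0.0873 with an estimated correlation). The Glycolysis list had 6 of its 12 measured genes higher, 1 lower and 5 not passing (7 and 2 adjusted over the list alone), with the enzymes PFKP and ENO1 at 0.98 ± 0.24 and 0.70 ± 0.12. The median was 0.37 (camera, adjusted p = 0.000388, and adjusted p = 0.243 with an estimated correlation). Of 14 measured genes of the Regulatory T cell list, 5 rose, 3 fell and 6 did not pass (6 and 3 adjusted over the list alone). Its median was 0.96 (camera, adjusted p = 0.0029, and adjusted p = 0.0995 with an estimated correlation). In the MHC class II list 2 of 12 measured genes rose, 0 fell and 10 did not pass (1 and 0 adjusted over the list alone). The median was 0.30 (camera, adjusted p = 0.00451, and adjusted p = 0.0873 with an estimated correlation). The Immediate early and heat shock list had 4 of its 13 measured genes higher, 1 lower and 8 not passing (4 and 1 adjusted over the list alone), with IER2 at 1.20 ± 0.14 and the heat shock gene DNAJB1 at -1.36 ± 0.25. Its median was 0.23 (camera, adjusted p = 0.00901, and adjusted p = 0.0995 with an estimated correlation).

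The remaining lists did not pass after 6 h with rATG at 10 µg/mL. Their camera adjusted p values were 0.343 for T cell identity, 0.822 for NK and cytotoxic, 0.502 for B cell, 0.921 for Monocyte, 0.206 for Dendritic cell, 0.875 for Neutrophil, 0.461 for Platelet, 0.822 for Erythroid, 0.45 for Proliferation, 0.121 for Complement and Fc receptors and 0.121 for Reference genes. The median and mean of the NK and cytotoxic, Neutrophil and Erythroid lists were negative (medians -0.12, -0.07 and -0.19) while the test pointed up. The Dendritic cell list had a negative median (-0.05) with a positive mean and test. Of the T cell identity list 3 genes rose and 7 fell out of 23 (3 and 8 adjusted over the list alone), and those that fell included the T cell receptor signalling genes LAT, LCK and ZAP70 (-0.96 ± 0.16, -0.75 ± 0.15 and -0.66 ± 0.12). Of 21 monocyte genes 2 rose and 4 fell (2 and 4 adjusted over the list alone), with TLR2, a receptor for bacterial lipopeptides, at 1.12 ± 0.28, MNDA at -2.30 ± 0.55, and CD14, the co-receptor for lipopolysaccharide, at -1.37 ± 0.42. CD14 had an adjusted p of 0.0155, and of 0.145 without rATG 6 h replicate 2 (range over the alternatives 0.00031 to 0.145). In total 2616 genes passed, 867 higher and 1749 lower, around a median over all genes of -0.17. Centring each array on its median removed that shift and gave 1234 higher and 851 lower, and 1687 genes passed without rATG 6 h replicate 2.

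**Figure D2:**
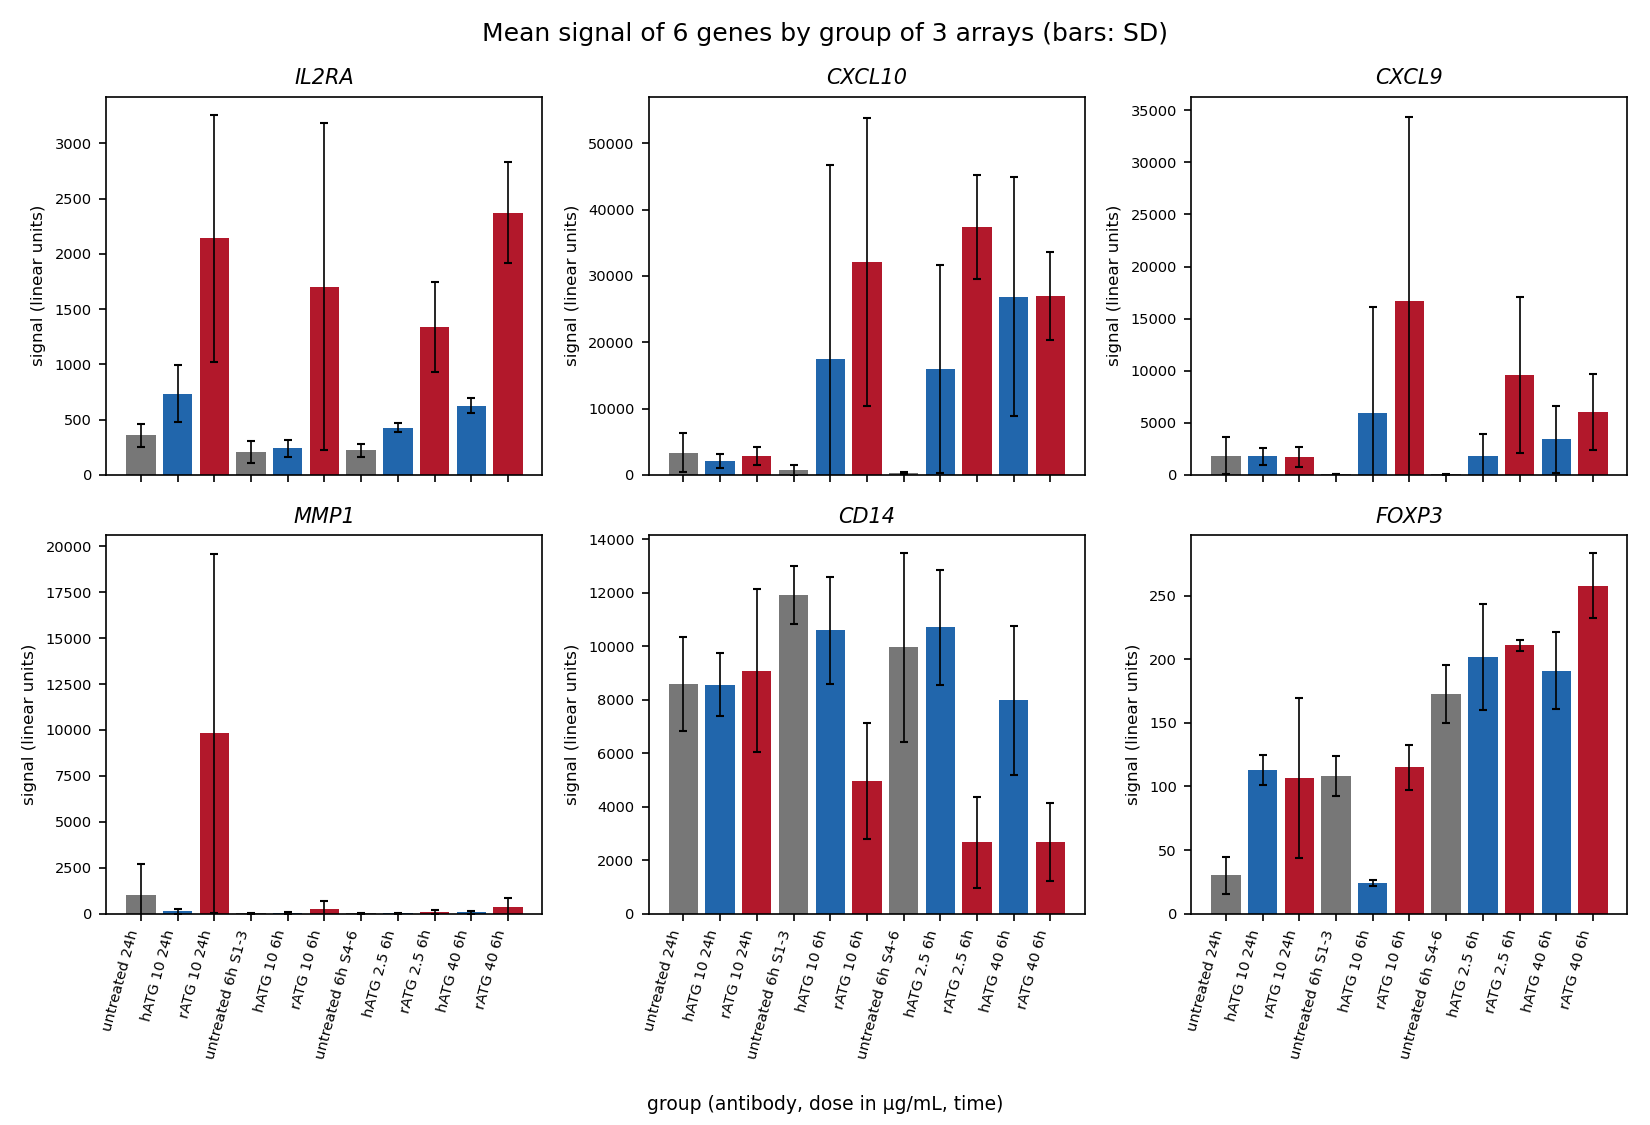
Mean signal (signal units, linear axes that differ between genes) of 6 genes in the 11 groups (grey untreated, blue hATG, red rATG), with error bars of 1 SD (n = 3) cut off at 0. CXCL10 rose from 684 ± 808 to 32100 ± 21700 signal units with rATG at 10 µg/mL and 6 h.

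With hATG at 10 µg/mL for 6 h, 1 gene passed (limma), out of 298 genes at an unadjusted p under 0.05. Those 298 are fewer than the share of 0.05 of the 8791 tested genes that no change would give on average. With the replicate block 536 genes had an unadjusted p under 0.05, more than that share. FOXP3, the transcription factor of regulatory T cells (chromosome X, 49250438 to 49264710), was lower with hATG at signals of 24.3 ± 2.39 against 108 ± 15.6 (adjusted p = 0.037). All 6 signals lay under the 40th percentile of their arrays, so no fold change is given. Its adjusted p ranged from 0.00695 to 1 over the alternatives and was 0.0851 with the replicate block. It was 0.179, 0.538 and 0.148 without untreated 6 h replicate 1, 2 or 3 and 0.128, 0.104 and 0.0537 without hATG replicate 1, 2 or 3. CXCL10 had a log2 fold change of 2.32 ± 1.27 (adjusted p = 1, and 0.381 to 1 over the alternatives), which was 0.06 without hATG replicate 1 and 4.04 without hATG replicate 3. IFNG, the interferon gamma gene, and TNF had 0.71 ± 0.73 and 1.07 ± 0.65 (adjusted p = 1 for both), which were -0.43 and -0.03 without hATG replicate 1. In the Interferon gamma response list 0 of 15 genes passed (0 and 0 adjusted over the list alone). The median was 0.97 (camera, adjusted p = 1.42e-08, and adjusted p = 0.495 with an estimated correlation). The T cell activation list had 0 of 25 genes passing (0 and 0 adjusted over the list alone). Its median was 0.40 (camera, adjusted p = 2.16e-06, and adjusted p = 0.495 with an estimated correlation). hATG 6 h replicate 1 had the highest ratios of the signals at the 3 prime and 5 prime ends of ACTB and GAPDH, a measure of RNA integrity, at 1.66 and 1.48. The count was 0 with that array left out together with the replicate block, a fit chosen after seeing the data, and 0 without any 1 of the 3 untreated arrays or hATG replicate 1, and 2 without hATG replicate 3. FOXP3 was called in other comparisons too (limma). At 24 h it was higher than untreated with hATG (113 against 30, adjusted p = 0.00091) and rATG (107 against 30, adjusted p = 0.00057). At 6 h it was higher with rATG than with hATG (115 against 24.3, adjusted p = 0.00011). Untreated cells had less at 24 h than at 6 h (30 against 108, adjusted p = 0.00026). Each group had at least 2 of 3 arrays under the 40th percentile, so no change can be separated from background.

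rATG and hATG at 10 µg/mL also differed at 6 h. CCL2 and CCL7 were higher with rATG (4.55 ± 0.95 and 4.23 ± 0.83), as were EMP1, an epithelial membrane protein (3.19 ± 0.34), and the lysosomal protease gene CTSL (3.15 ± 0.47). ALDH1A2, an enzyme of retinoic acid synthesis, was higher too (at least 1.92), as were IL10 (2.40 ± 0.53) and IL1RN, the interleukin 1 receptor antagonist (2.16 ± 0.43). LEP was lower by at least 1.47, and the dipeptidase gene DPEP2 was lower (-2.28 ± 0.36). Of 25 T cell activation genes 23 were higher and 0 lower (24 and 0 adjusted over the list alone), with TNFRSF9 and CD69, an early activation antigen, at 3.69 ± 0.60 and 1.53 ± 0.27. The median was 1.67 (camera, adjusted p = 7.67e-18, and adjusted p = 0.0918 with an estimated correlation). Of the Interferon gamma response list 12 of 15 were higher and 0 lower (13 and 0 adjusted over the list alone). Its median was 2.09 (camera, adjusted p = 2.05e-07, and adjusted p = 0.25 with an estimated correlation). In total 2177 genes differed, 697 higher and 1480 lower, around a median over all genes of -0.14. With that shift removed by centring on the median 1059 were higher and 751 lower, 440 passed when only the groups compared were fitted, 1258 without rATG 6 h replicate 2, and 3040 with hATG replicate 1 left out together with the replicate block.

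The other set of arrays held a lower and a higher dose at 6 h. With rATG at 2.5 µg/mL CXCL11, CXCL9 and CXCL10 rose by at least 6.22, at least 5.57 and 7.06 ± 1.27, GBP1, an interferon-induced GTPase, by 4.51 ± 0.75, and TNF, XCL1 and IL2RA by 3.20 ± 0.65, 3.32 ± 0.56 and 2.48 ± 0.45. LEP and VNN1 fell by at least 2.36 and at least 3.13. The transcription factor CEBPD fell (-2.50 ± 0.34), as did CD14 and the complement receptor C5AR1 (-2.05 ± 0.42 and -1.60 ± 0.33). Of 25 measured genes of the T cell activation list, 23 rose, 0 fell and 2 did not pass (23 and 0 adjusted over the list alone). The median was 1.75 (camera, adjusted p = 1.8e-22, and adjusted p = 0.0355 with an estimated correlation). In the Interferon gamma response list 12 of 15 measured genes rose, 0 fell and 3 did not pass (14 and 0 adjusted over the list alone). Its median was 2.80 (camera, adjusted p = 1.04e-13, and adjusted p = 0.147 with an estimated correlation). The NF-kappaB targets list had 10 of its 14 measured genes higher, 0 lower and 4 not passing (12 and 0 adjusted over the list alone). The median was 1.22 (camera, adjusted p = 2.96e-10, and adjusted p = 0.147 with an estimated correlation). In total 1743 genes passed, 705 higher and 1038 lower, around a median over all genes of -0.14, and 2624 with the replicate block. Centring on the median gave 1162 higher and 413 lower, and 1084 genes passed without rATG 2.5 µg/mL replicate 3.

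With rATG at 40 µg/mL the same chemokines rose, CXCL11 by at least 5.86, CXCL9 by at least 5.20 and CXCL10 by 6.59 ± 1.27. CH25H, which makes the oxysterol 25-hydroxycholesterol, rose by at least 3.43, IL2RA by 3.34 ± 0.45 and IL1RN by 3.14 ± 0.43. LEP fell by at least 2.36. The monocyte genes CD14 and CSF1R fell (-1.96 ± 0.42 and -1.42 ± 0.28), as did the B cell genes TCL1A and CD79B (-2.08 ± 0.54 and -1.96 ± 0.45). Of 25 measured genes of the T cell activation list, 22 rose, 0 fell and 3 did not pass (24 and 0 adjusted over the list alone). Its median was 2.04 (camera, adjusted p = 1.12e-19, and adjusted p = 0.0623 with an estimated correlation). In the Interferon gamma response list 14 of 15 measured genes rose, 0 fell and 1 did not pass (14 and 0 adjusted over the list alone). The median was 2.79 (camera, adjusted p = 4.46e-11, and adjusted p = 0.242 with an estimated correlation). The B cell list had 1 of its 18 measured genes higher, 8 lower and 9 not passing (1 and 8 adjusted over the list alone), and CR2, the complement receptor of B cells, was the 1 that rose (1.66 ± 0.31). The list did not pass (median -0.68, camera, adjusted p = 0.186, and adjusted p = 0.955 with an estimated correlation). In total 2500 genes passed, 963 higher and 1537 lower, around a median of -0.15, and centring on the median gave 1491 higher and 717 lower.

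With hATG at 2.5 µg/mL 0 genes passed (limma), and 4 passed with the replicate block. Without the block 326 genes had an unadjusted p under 0.05, also fewer than a share of 0.05 of the 8791 tested genes. With the block 585 genes did, more than that share. The Interferon gamma response list had 0 of 15 genes passing (9 and 0 adjusted over the list alone). Its median was 1.16 (camera, adjusted p = 8.72e-17, and adjusted p = 0.222 with an estimated correlation). The T cell activation list also had 0 of 25 genes passing (0 and 0 adjusted over the list alone). The median was 0.35 (camera, adjusted p = 2.4e-05, and adjusted p = 0.528 with an estimated correlation).

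With hATG at 40 µg/mL CXCL10 and CXCL11 rose by 6.25 ± 1.27 and at least 3.86, GBP1 by 4.04 ± 0.75 and EGR3 by 2.43 ± 0.48. ICOS, an inducible co-stimulator of T cells, and the lymphocyte factor IRF4 rose by 1.47 ± 0.29 and 1.58 ± 0.33. LEP fell by at least 2.21, and CEBPD and DNAJB1 fell (-1.60 ± 0.34 and -1.26 ± 0.25). Of 25 measured genes of the T cell activation list, 5 rose, 0 fell and 20 did not pass (18 and 0 adjusted over the list alone). Its median was 1.12 (camera, adjusted p = 2.24e-25, and adjusted p = 0.0204 with an estimated correlation). In the Interferon gamma response list 4 of 15 measured genes rose, 0 fell and 11 did not pass (10 and 0 adjusted over the list alone). The median was 1.89 (camera, adjusted p = 1.54e-21, and adjusted p = 0.0499 with an estimated correlation). The NF-kappaB targets list had 2 of its 14 measured genes higher, 0 lower and 12 not passing (10 and 0 adjusted over the list alone). Its median was 0.70 (camera, adjusted p = 3.4e-13, and adjusted p = 0.0499 with an estimated correlation). In total 60 genes passed, 39 higher and 21 lower, and 253 with the replicate block. Every gene named for this comparison lost its call without at least 1 of the 6 arrays. CXCL11 also lost it without the filter, with a pseudocount of 64, with quantile normalization or median centring, with the median of a gene's probe sets, with all probe sets and without the trend. LEP lost it with a pseudocount of 1 and IRF4 with the median of its probe sets. In total 2, 3 and 27 genes passed without untreated replicate 1, 2 or 3, and 5, 33 and 1 without hATG 40 µg/mL replicate 1, 2 or 3.

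**Figure D3:**
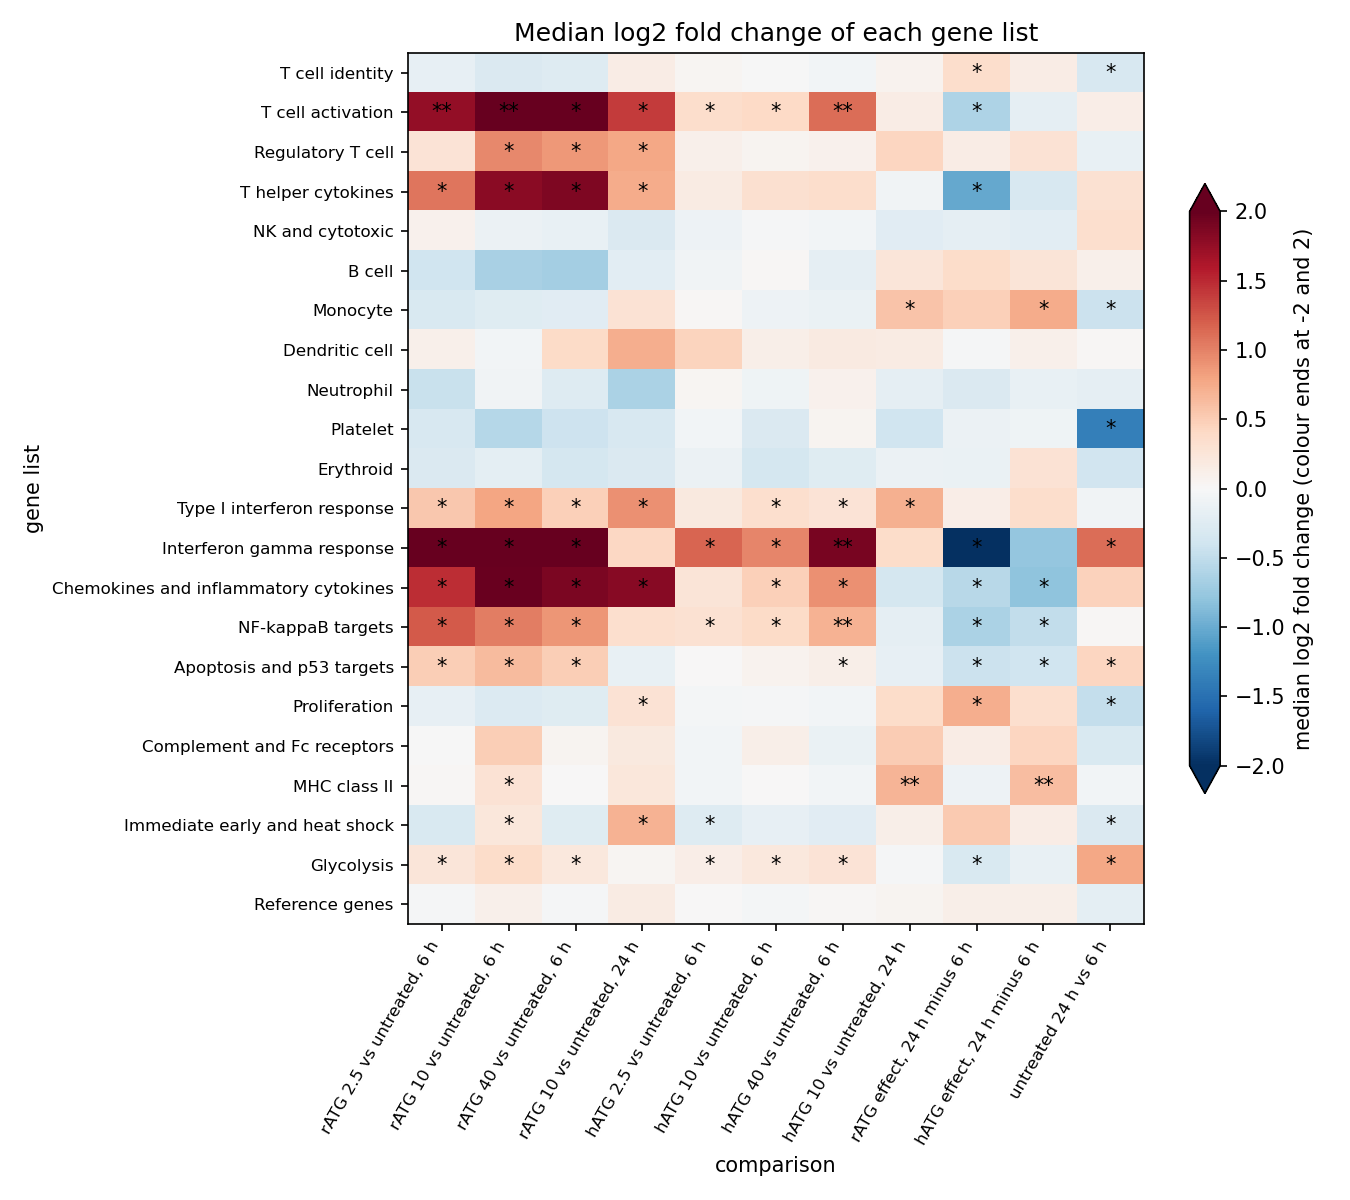
Median log2 fold change of each of the 22 gene lists (vertical) in 11 of the 19 comparisons (horizontal), with the colour scale ending at -2 and 2; 1 star marks a list that passed camera and a double star a list that also passed with an estimated correlation. T cell activation had medians of 1.75 to 2.04 with rATG at 6 h.

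The antibodies were also compared at each of these doses. At 2.5 µg/mL XCL1 and TNFRSF9 were higher with rATG than with hATG (2.94 ± 0.56 and 2.85 ± 0.60), as were TNFSF14, a TNF family ligand of T cells (1.78 ± 0.32), GADD45A (1.92 ± 0.21) and SERPINE2, a protease inhibitor (2.22 ± 0.25), and CD14 and CEBPD were lower (-2.21 ± 0.42 and -1.58 ± 0.34). Of 25 T cell activation genes 19 were higher and 0 lower (21 and 0 adjusted over the list alone). The median was 1.33 (camera, adjusted p = 4.89e-23, and adjusted p = 0.0318 with an estimated correlation). In total 748 genes differed, 332 higher and 416 lower, around a median of -0.10, and 1536 with the replicate block. Centring on the median gave 598 higher and 158 lower, 300 genes passed when only the groups compared were fitted, 380 and 276 without hATG 2.5 µg/mL replicate 1 or 2, and 322 and 250 without rATG 2.5 µg/mL replicate 2 or 3.

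At 40 µg/mL CH25H was higher with rATG (at least 3.52), as were CISH and SOCS2, feedback inhibitors of cytokine signalling (2.74 ± 0.51 and 2.97 ± 0.44), the growth factor HBEGF (3.09 ± 0.48) and HSPE1 (1.07 ± 0.17), and LAT and the neuropeptide receptor VIPR1 were lower (-0.98 ± 0.16 and -2.15 ± 0.46). 7 of 12 T helper cytokine genes were higher and 0 lower (9 and 0 adjusted over the list alone). Its median was 1.59 (camera, adjusted p = 3.83e-08, and adjusted p = 0.243 with an estimated correlation). In the Interferon gamma response list 0 of 15 genes passed (0 and 0 adjusted over the list alone). The median was 0.52 (camera, adjusted p = 0.038, and adjusted p = 0.857 with an estimated correlation). In total 753 genes differed, 377 higher and 376 lower, and 1410 with the replicate block. Centring on the median gave 584 higher and 170 lower, 450 genes passed when only the groups compared were fitted, 375 and 424 without hATG 40 µg/mL replicate 1 or 2, and 330 without rATG 40 µg/mL replicate 1.

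**Figure D4:**
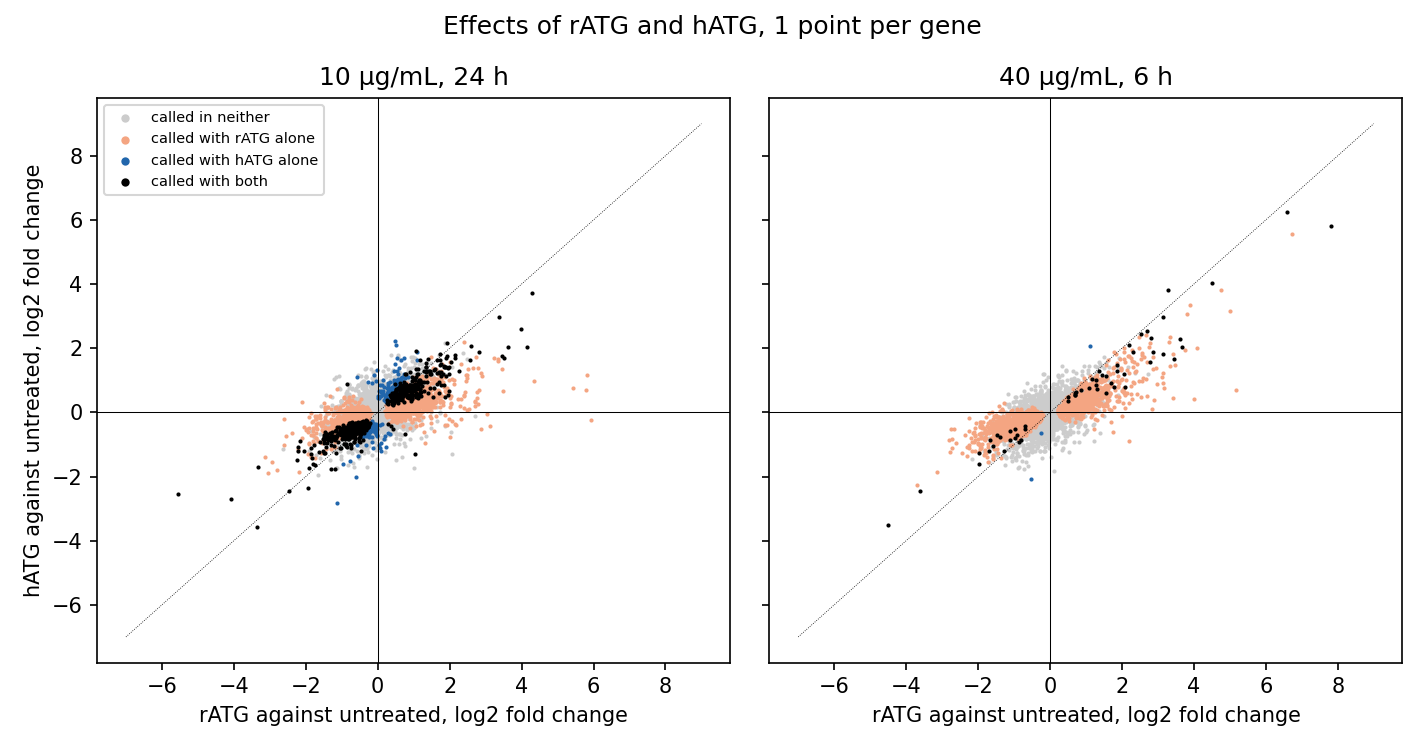
Log2 fold change against untreated cells with rATG (horizontal) and hATG (vertical) for the 8791 genes at 10 µg/mL and 24 h and at 40 µg/mL and 6 h, with the dotted line marking equal effects. At 10 µg/mL and 24 h 554 genes passed in the same direction with both antibodies and 6 in opposite directions.

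The effects of the antibodies were set side by side across genes, which are not independent replicates. At 10 µg/mL and 24 h 245 genes rose with both antibodies and 309 fell with both. Simulated draws with no change, which shared the untreated arrays in the same way, gave at most 1 gene called the same way with both. Pearson's r across genes was 0.633 there. At 6 h it was 0.654 at 2.5 µg/mL, 0.479 at 10 µg/mL and 0.747 at 40 µg/mL, where 57 of the 60 genes called with hATG were called the same way with rATG. The shared untreated arrays alone gave a median r of 0.499 to 0.505 and a highest r of 0.533 to 0.545 over 100 simulated draws. At 10 µg/mL and 6 h r was no higher than that, but the covariance across genes was 0.104 against a highest simulated value of 0.0615. The draws gave every group the same spread and held no array that stands apart, as hATG 6 h replicate 1 does. The covariance was not computed without that array, so it cannot show a shared effect there. The draws also took genes independently of one another and held no effect of the replicate number. The simulated ranges of r, covariance and shared calls may therefore be too narrow, and they cannot by themselves show a shared effect. With the replicate block 1067 genes at 10 µg/mL and 24 h, 242 at 40 µg/mL and 4 at 2.5 µg/mL passed the same way with both. Between the separate sets of arrays, 1300 genes passed the same way with rATG at 10 and at 2.5 µg/mL and 6 h and 2 in opposite ways (r = 0.763 across genes), and 1674 at 10 and at 40 µg/mL with 2 opposite (r = 0.784). For hATG those correlations were 0.232 and 0.312, and 56 of the 60 genes called at 40 µg/mL had the same sign at 10 µg/mL.

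Dose was tested within the other set of arrays, as 40 against 2.5 µg/mL. With rATG 0 genes passed (limma), 3 passed with the replicate block and 1 passed without rATG 2.5 µg/mL replicate 1. An unadjusted p under 0.05 was found for 374 genes, and for 689 with the block. The B cell list was lower at 40 µg/mL, with 0 of 18 genes passing (0 and 0 adjusted over the list alone). Its median was -0.54 (camera, adjusted p = 0.000601, and adjusted p = 0.998 with an estimated correlation). For hATG 0 genes passed, and 0 with the replicate block. An unadjusted p under 0.05 was found for 232 genes, and for 442 with the block. T cell activation was higher with hATG at 40 than at 2.5 µg/mL. The median was 0.79 (camera, adjusted p = 2.77e-26, and adjusted p = 0.0172 with an estimated correlation). None of its 25 genes passed over all genes (11 and 0 adjusted over the list alone). The NF-kappaB targets list had 0 of 14 genes (0 and 0 adjusted over the list alone). Its median was 0.45 (camera, adjusted p = 1.04e-10, and adjusted p = 0.145 with an estimated correlation). For the difference between antibodies in the effect of dose 0 genes passed, 2 with the replicate block and 1 without rATG 2.5 µg/mL replicate 1. An unadjusted p under 0.05 was found for 202 genes, and for 417 with the block. T cell activation was lower in that difference, with 0 of 25 genes (0 and 0 adjusted over the list alone). The median was -0.62 (camera, adjusted p = 5.27e-09, and adjusted p = 0.381 with an estimated correlation). In each of these dose comparisons fewer than a share of 0.05 of the 8791 tested genes had an unadjusted p under 0.05 in the fit without the block. With the block the 689 genes for rATG were more than that share, and the 442 for hATG were close to it. The shortfall therefore depends on the fit and does not show that dose had no effect.

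Time was tested at 10 µg/mL as the effect at 24 h minus the effect at 6 h. The rATG effect on HK3 was more positive at 24 h (3.80 ± 0.49), as was that on MCM4, MCM5 and MCM2 (1.81 ± 0.32, 1.80 ± 0.36 and 1.64 ± 0.36) and on LAT and ITGAM (1.27 ± 0.23 and 1.94 ± 0.31), and that on GADD45A was lower (-2.05 ± 0.30). For the Interferon gamma response 6 of 15 genes were lower and 0 higher (0 and 10 adjusted over the list alone). Its median was -2.10 (camera, adjusted p = 1.5e-08, and adjusted p = 0.528 with an estimated correlation). In total 912 genes passed, 641 higher and 271 lower, around a median of 0.13, and 1580 with the replicate block. Of the 912 genes 552 were also called between 24 h and 6 h in untreated cells, in the opposite direction, and 19 in the same direction. Both comparisons use the same untreated arrays, so part of the opposition is built in. Centring on the median gave 210 higher and 437 lower, 470 genes passed when only the groups compared were fitted, 597 without untreated 24 h replicate 2 and 544 without rATG 24 h replicate 1.

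The hATG effect on HK3, CST3 and CD74 was more positive at 24 h than at 6 h (3.05 ± 0.49, 1.23 ± 0.21 and 0.87 ± 0.16), and that on CREM was lower (-1.79 ± 0.29). In the MHC class II list 1 of 12 genes was higher and 0 lower (5 and 0 adjusted over the list alone). The median was 0.62 (camera, adjusted p = 0.000186, and adjusted p = 0.0311 with an estimated correlation). In total 104 genes passed, 42 higher and 62 lower, 17 when only the groups compared were fitted, and 418 with hATG 6 h replicate 1 left out together with the replicate block. Centring on the median gave 23 higher and 129 lower, and 44, 28, 38 and 36 genes passed without untreated 24 h replicate 1, hATG 24 h replicate 1, untreated 6 h replicate 1 or untreated 6 h replicate 3. The change with time differed between the antibodies at 37 genes, 28 higher and 9 lower in rATG minus hATG. MHC class II was lower in that difference, with 1 of 12 genes lower and 0 higher (0 and 6 adjusted over the list alone). Its median was -0.74 (camera, adjusted p = 2.03e-08, and adjusted p = 0.000726 with an estimated correlation). The 37 became 13 with median centring (7 higher, 6 lower) and 27 with quantile normalization (17 higher, 10 lower). It was 24 with a pseudocount of 1, 22 without the filter and 0 when only the groups compared were fitted, and 543 with hATG 6 h replicate 1 left out together with the replicate block. Without hATG 24 h replicate 1 or 3 it was 15 or 8, without rATG 24 h replicate 1, 2 or 3 it was 19, 20 or 22, without hATG 6 h replicate 3 it was 23, and without rATG 6 h replicate 1 or 3 it was 18 or 63.

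Untreated cells changed between 6 h and 24 h of culture, the background for the comparisons over time, and their ACTB 3 prime to 5 prime ratio rose from 1.24 ± 0.03 to 1.34 ± 0.0173. Their GAPDH ratio did not rise (1.07 ± 0.134 at 6 h and 1.03 ± 0.061 at 24 h). The glycolytic genes GPI, PFKP, TPI1 and ENO1 were higher at 24 h, by 2.66 ± 0.22, 1.93 ± 0.24, 1.21 ± 0.14 and 1.16 ± 0.12. The inhibitory Fc receptor FCGR2B and the collagenase gene MMP9 rose by 3.48 ± 0.45 and 3.28 ± 0.76. TUBB1, the tubulin of platelets, fell by at least 2.80. HPSE, which encodes heparanase, fell (-3.70 ± 0.35), as did the T cell genes CD8A and CCR7 (-1.46 ± 0.36 and -1.16 ± 0.18). Of 12 measured genes of the Glycolysis list, 8 rose, 0 fell and 4 did not pass (8 and 0 adjusted over the list alone). The median was 0.78 (camera, adjusted p = 1.05e-08, and adjusted p = 0.283 with an estimated correlation). In the Platelet list 0 of 11 measured genes rose, 7 fell and 4 did not pass (0 and 7 adjusted over the list alone). Its median was -1.37 (camera, adjusted p = 4e-04, and adjusted p = 0.283 with an estimated correlation). The T cell identity list had 1 of its 23 measured genes higher, 8 lower and 14 not passing (1 and 8 adjusted over the list alone). The median was -0.32 (camera, adjusted p = 0.012, and adjusted p = 0.5 with an estimated correlation). In total 2252 genes passed, 935 higher and 1317 lower, and centring on the median gave 1163 higher and 908 lower.

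Over all 19 comparisons 135 of the calls on the 22 lists passed with the preset correlation, 103 higher and 32 lower, and 11 passed with an estimated correlation. Of those, 5 were T cell activation, with rATG at 10 and 2.5 µg/mL and with hATG at 40 µg/mL at 6 h, in rATG against hATG at 2.5 µg/mL and in hATG at 40 against 2.5 µg/mL. The others were Interferon gamma response and NF-kappaB targets with hATG at 40 µg/mL, MHC class II with hATG at 24 h and in both comparisons of time that involve hATG, and Immediate early and heat shock in rATG against hATG at 24 h.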

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

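The tests on FOXP3 and the comparisons of CD14 with other monocyte genes were chosen only after the results were seen. The other tests of this part were chosen before them.

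The rATG effect at 10 µg/mL differed between 24 h and 6 h at 912 genes (limma, 544 to 938 when 1 array was left out at a time), as a test of the difference itself showed. It was more positive at 24 h for the matrix genes MMP12 (5.0), COL6A3 (4.90) and MMP10 (3.49), for HK3 (3.80) and for AGMAT (3.54). The replication genes MCM4 (1.81), MCM5 (1.80), MCM2 (1.64) and MCM3 (1.15) moved the same way. So did the monocyte and Fc receptor genes ITGAM (1.94), SERPINA1 (1.63), CSF1R (1.37), S100A8 (1.06) and FCGR2A (0.90), and the T cell genes CD27 (1.69), LAT (1.27), CCR7 (1.07) and CD4 (1.04). The chaperone genes BAG3 (1.02) and HSP90AA1 (0.76) and the complement regulator CD46 (0.57) were also higher. It was lower at 24 h for the chemokines CXCL11 (-7.05), CXCL9 (-6.03) and CXCL10 (-5.75), for IDO1 (-4.66), MET (-4.25), IL10 (-2.75) and IL6 (-2.50). The stress and maturation genes GADD45A (-2.05), CD83 (-1.43), BCL2L11 (-1.42) and PMAIP1 (-1.32) were lower too. FCGR2A moved this way in 2 of 3 same-numbered pairs. FOXP3 was called too (1.27, 2 of 3 pairs), but all untreated arrays and 2 of 3 rATG arrays at each time lay under the 40th percentile, so no change can be separated from background. The sizes for MMP12, COL6A3, MMP10, AGMAT, CXCL11, CXCL9 and IL10 are not exact, since all 3 arrays of at least 1 of the 4 groups lay under the 40th percentile. Among these genes, the calls of HK3, AGMAT, LAT, CCR7, ITGAM, SERPINA1, GADD45A and the 4 MCM genes held in every alternative and without each array. By list, T cell identity (0.35) and Proliferation (0.73) had higher medians. T cell activation (-0.62), T helper cytokines (-1.03), Interferon gamma response (-2.10), Chemokines and inflammatory cytokines (-0.55), NF-kappaB targets (-0.63), Apoptosis and p53 targets (-0.43) and Glycolysis (-0.30) had lower ones (camera, adjusted p up to 0.033, and adjusted p = 0.292 to 0.744 with an estimated correlation).

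The hATG effect differed between the times at 104 genes (28 to 125 when 1 array was left out at a time). It was more positive at 24 h for LILRA3 (3.75), HK3 (3.05), ZNF696 (2.99), ZCCHC24 (2.46), ITGAM (1.36), SERPINA1 (1.34), CST3 (1.23) and CD74 (0.87). It was lower for GPR132 (-4.20), TKTL1 (-3.59), MET (-2.85), RPP25 (-2.0), CREM (-1.79) and MCM6 (-0.70). FOXP3 was called too (3.15), but it lay under the 40th percentile on every array of all 4 groups, so no change can be separated from background. The sizes for ZNF696, ZCCHC24, GPR132 and RPP25 are not exact, since at least 1 of the groups lay wholly under it. Of these genes HK3, CREM and CST3 kept their calls in every alternative and without each array. So did CD74, apart from the alternative that also asked for an absolute log2 fold change of at least 1. The medians of the Monocyte (0.75) and MHC class II (0.62) lists were higher and those of Chemokines and inflammatory cytokines (-0.80), NF-kappaB targets (-0.50) and Apoptosis and p53 targets (-0.39) were lower. With an estimated correlation the adjusted p was 0.0311 for MHC class II and 0.44 to 0.852 for the others.

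The difference between rATG and hATG changed with time at 37 genes (8 to 63 when 1 array was left out at a time). It was higher at 24 h for MMP10 (4.30), the cytokine gene RETN (2.32), PFAS (1.85), PMEPA1 (1.81), the cholesterol transporter ABCG1 (1.76), MCM6 (0.99) and CD7 (0.86). It was lower for HSPG2 (-3.18), EMP1 (-2.57), CD36 (-2.39), SCARB2 (-1.76) and HLA-DMB (-1.37). At least 1 of the 4 groups lay wholly under the 40th percentile for MMP10, RETN and HSPG2, so their sizes are not exact. FOXP3 was called too (-1.88), but all hATG arrays and 2 of 3 rATG arrays at each time lay under it, so no change can be separated from background. Each of these calls was lost in at least 1 alternative or without at least 1 array. T cell identity (0.25) and Proliferation (0.68) had higher list medians. T helper cytokines (-0.89), Monocyte (-0.23), Type I interferon response (-0.36), Interferon gamma response (-1.51), Apoptosis and p53 targets (-0.18) and MHC class II (-0.74) had lower ones, with adjusted p = 0.000726 for MHC class II and 0.431 to 0.737 for the others with an estimated correlation.

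With hATG at 10 µg/mL for 6 h 1 gene was called, while control probe sets, which no comparison used, set 1 of the arrays apart. In hATG 10 µg/mL 6 h replicate 1 the ratio of the 3 prime to the 5 prime signal was 1.48 for GAPDH and 1.66 for ACTB, against at most 1.22 and 1.36 on untreated arrays. The mean ACTB ratio was also lower than in untreated cells with rATG and hATG in every group but hATG at 10 µg/mL and 6 h, and higher in untreated cells at 24 h than at 6 h. The mean GAPDH ratio differed less between groups. In untreated cells it was 1.03 at 24 h and 1.07 at 6 h, the other direction from ACTB. A difference in RNA quality between groups stays open as a technical explanation of part of the changes with rATG, with hATG and over time, and it was not tested. A candidate explanation was that the 1 array that stands apart hid the changes. Without it 0 genes were called, but that fit has fewer hATG arrays, and leaving out an array can remove calls by itself. With hATG at 40 µg/mL the count fell from 60 to between 1 and 33 when 1 array was left out. So the count of 0 cannot tell a hidden effect from none. Another was that the hATG effect differed between 6 h and 24 h only through that array, but without it 102 genes differed over time, against 104 with it. A small or variable effect of hATG at this dose and time stays open as a biological explanation and was not tested.

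FOXP3 was lower with hATG at 10 µg/mL and 6 h in 3 of 3 same-numbered pairs. A signal near the background of the array is a candidate explanation, since FOXP3 was above the 40th percentile of its array on 0 of the 6 arrays. With hATG at 24 h FOXP3 was called the other way (113 against 30, limma, adjusted p = 0.00091). In untreated cells it was lower at 24 h than at 6 h (30 against 108, adjusted p = 0.00026). Every array of those groups also lay under the 40th percentile. An hATG effect at 6 h, at every dose or only in the set of replicates S1 to S3, stays open as a biological explanation. The log2 fold changes at 2.5 and 40 µg/mL, 0.20 (SE 0.28) and 0.13, decide nothing about it, since all signals of the pattern lay near background. The call at 10 µg/mL and 6 h was lost without any 1 of the 6 arrays (limma, adjusted p 0.0537 to 0.538). The fitted log2 fold change, which is not exact, was -1.61 and stayed at -1.67 to -1.51 in those fits. So no single array carried the difference, which cannot be separated from background.

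CD14 was lower after 6 h with rATG at each dose, by log2 fold changes of -1.37, -2.05 and -1.96 at 10, 2.5 and 40 µg/mL. If fewer monocytes were in the culture, other monocyte genes should fall about as far, but the medians of the other 20 genes of the Monocyte list were -0.22, -0.29 and -0.21 (interquartile ranges 0.66, 0.77 and 0.64), and TLR2 rose at each dose and FCER1G at 10 and 40 µg/mL. Other members fell with CD14, namely CSF1R and MNDA at each dose and VCAN at 10 and 2.5 µg/mL, and MNDA fell by -2.30 at 10 µg/mL, further than CD14. So the medians argue against fewer monocytes as the whole cause, while a smaller loss of monocytes stays open. The scaling between arrays is unlikely as the cause, since quantile normalization gave -1.44 at 10 µg/mL. A change in CD14 transcripts of the monocytes themselves may account for these values, and it is a hypothesis found and examined on the same data. At 10 µg/mL the call was lost without rATG 6 h replicate 2 (log2 fold change -0.93, adjusted p = 0.145, range over the alternatives 0.00031 to 0.145).

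Other splits of the same arrays were counted for each comparison. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. In 14 comparisons 1 split, the real one, gave as many called genes. The real count and the highest of the other splits were 2538 and 1 for rATG, 718 and 2 for hATG and 1120 and 1 for rATG against hATG at 10 µg/mL and 24 h. At 10 µg/mL and 6 h they were 2616 and 0 for rATG and 2177 and 359 for rATG against hATG. The split with 359 genes exchanged rATG replicate 3 and hATG replicate 1. In that comparison the lowest residual correlation of a same-numbered pair was 0.084, under 0.1, and the median was 0.142. At 2.5 µg/mL they were 1743 and 0 for rATG and 748 and 1 between antibodies, and at 40 µg/mL 2500 and 0, 60 and 0, and 753 and 0 for rATG, hATG and the difference. They were 912 and 1, 104 and 0, and 37 and 0 for the changes over time with rATG, with hATG and between them, and 2252 and 3 for untreated cells. For hATG at 10 µg/mL and 6 h 2 of the 10 splits gave as many, with 1 gene against 2. For hATG at 2.5 µg/mL and the 3 comparisons of dose the real count was 0, all 10 splits gave as many, and the highest of the others were 2, 1 (rATG), 0 (hATG) and 0 (between them). Where every same-numbered pair had a residual correlation above 0.1, the other splits that part all pairs gave 0 genes in each comparison.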

How the results depend on the processing

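The alternative that left out hATG 10 µg/mL 6 h replicate 1 together with the replicate block was chosen only after the results were seen. Of 762 calls on named genes, 0 changed direction without an array, and 3787 of 4938 values with 1 array left out stayed called. With the block 761 stayed called, and FOXP3 in hATG against untreated cells at 10 µg/mL and 6 h was the exception. Fewest stayed called, 573, when only the groups compared were fitted, which leaves fewer arrays to estimate the spread. The others kept 598 to 762 of 762, and a filter at the 60th percentile kept 670 of the 671 it still tested. Signals under the 40th percentile of an array cannot be separated from background, and fitted values below are not exact where a group lay wholly under it. These are IL2 with hATG at 24 h and 6 h (both groups) and with rATG at 24 h, IL10 with rATG at 24 h, and FOXP3 with hATG at 6 h and in rATG against hATG at 24 h. Their changes of sign show nothing that can be separated from background. Where an alternative below tests more features (no filter, all probe sets), calls fewer by its own threshold (log2 fold change of at least 1) or uses fewer arrays, that is part of its construction. For the other changes below the cause was not tested.

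For hATG at 10 µg/mL and 6 h the 1 called gene became 0 without the filter, at the 60th percentile, with a pseudocount of 64, with all probe sets, with the replicate block, with only the groups compared, and with the array that stands apart left out together with the block. It became 2 with a pseudocount of 1, with a random block and with array weights. For the difference between antibodies over time the 37 genes became 22 without the filter, 24 with a pseudocount of 1, 13 with median centring and 23 without the trend. With all probe sets 3931 probe sets passed for rATG at 24 h, 4089 for rATG at 10 µg/mL and 6 h, 3393 for rATG against hATG there, 3965 for rATG at 40 µg/mL, 3475 for untreated cells and 1 for rATG at 40 against 2.5 µg/mL.

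With the replicate block the count was 1430 for hATG and 1848 for rATG against hATG at 24 h. It was 2624 for rATG, 4 for hATG and 1536 for their difference at 2.5 µg/mL, and 253 for hATG and 1410 for the difference at 40 µg/mL. The block gave 1580, 476 and 343 for the changes over time with rATG, with hATG and between them, 3 for the rATG dose and 2 for the difference between antibodies over dose. It gave 1067, 4 and 242 genes called the same way with both antibodies at 10 µg/mL and 24 h and at 2.5 and 40 µg/mL. It also took the 1 gene for hATG at 10 µg/mL and 6 h to 0, and it moved no other count by over 1.5 times. A random block gave 1267 for hATG at 24 h, 1357 for the difference at 2.5 µg/mL, 187 for hATG and 1246 for the difference at 40 µg/mL, and 1397, 328 and 268 for the changes over time. Array weights gave 1 for hATG at 2.5 µg/mL, 1225 for the difference there and 167 for hATG at 40 µg/mL. Without the trend hATG at 40 µg/mL gave 32 and the hATG effect over time 65.

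With a log2 fold change of at least 1 the counts for rATG, hATG and their difference at 10 µg/mL and 24 h were 732, 137 and 268. They were 731 for rATG and 526 for the difference at 10 µg/mL and 6 h, 475 and 171 at 2.5 µg/mL, and 748, 33 and 167 for rATG, hATG and the difference at 40 µg/mL. They were 395, 40 and 24 for the changes over time and 655 for untreated cells. With only the groups compared the count was 346 for hATG at 24 h, 440, 300 and 450 for the difference between antibodies at 10, 2.5 and 40 µg/mL and 6 h, and 470, 17 and 0 for the changes over time. With the array that stands apart left out together with the block it was 418 for the hATG effect over time and 543 for the difference between antibodies over time. The 135 list calls became 11 with an estimated correlation. They became 78 with fry, which tests a list against no change and not against the other genes, with 67 calls lost and 10 gained. The others were 131 with fry and the block (56 lost), 153 with camera and the block (0 lost), and 127 with quantile normalization (12 lost).

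When 1 array was left out at a time, counts ranged from 2035 to 2398 for rATG, 367 to 646 for hATG and 656 to 1055 for their difference at 10 µg/mL and 24 h. At 10 µg/mL and 6 h they ranged from 1687 to 2593, 0 to 2 and 1258 to 2200 in the same order. At 2.5 µg/mL they ranged from 1084 to 1659, 0 to 0 and 250 to 811, and at 40 µg/mL from 1802 to 2179, 1 to 33 and 330 to 681. The ranges were 0 to 1 for the rATG dose, 0 to 0 for the hATG dose and 0 to 1 for the difference between antibodies over dose. They were 544 to 938, 28 to 125 and 8 to 63 for the changes over time, and 1795 to 2031 for untreated cells.

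The following values changed sign, and of these only HK2 and CD46 were called. With a pseudocount of 1 the log2 fold change of IL10 with rATG at 24 h was 0.01, and with array weights it was 0.28. With a pseudocount of 64 IL2 with hATG at 10 µg/mL and 6 h was -0.01, and with array weights CD2 there was 0.01. With quantile normalization CD14 in rATG against hATG at 24 h and PRF1 with rATG at 10 µg/mL and 6 h were both -0.01. Median centring gave -0.09 for CD14 with hATG at 24 h. With the median of a gene's probe sets HK2 was 0.32 with rATG at 24 h, 0.23 with rATG at 10 µg/mL and 6 h and 0.08 in rATG against hATG there, where CD46 was 0.14. The NK and cytotoxic list pointed the other way with rATG at 10 µg/mL and 6 h (adjusted p 0.606 with fry, 0.0215 with fry and the block, 0.915 with camera and the block and 0.911 with quantile normalization), and in rATG against hATG there (0.67, 0.0472, 0.918 and 0.739).

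Without 1 array at a time, uncalled log2 fold changes with rATG at 24 h ranged from -0.51 to 0.41 for IL10, -0.71 to 0.99 for CXCL10, -1.25 to 0.30 for IL6, -0.14 to 0.35 for CD14 and -0.02 to 0.88 for IL2. With hATG at 24 h they ranged from -0.13 to 0.16 for CD14, -1.19 to 0.51 for CXCL10, -0.82 to 0.14 for IL2 and -0.01 to 0.24 for CD2. In rATG against hATG at 24 h they ranged from -0.15 to 0.35 for CD14, -0.03 to 0.29 for PRF1 and -0.57 to 0.15 for FOXP3. For hATG at 10 µg/mL and 6 h the ranges were -0.47 to 0.52 for CTLA4, -0.26 to 0.81 for IL10, -0.47 to 0.49 for IL2, -0.33 to 0.07 for PRF1, -0.25 to 0.11 for CD2 and -0.09 to 0.56 for IL2RA. There they were also -0.43 to 1.34 for IFNG, -0.03 to 1.77 for TNF, -0.01 to 0.62 for CD69 and -0.21 to 0.01 for CD3E. PRF1 ranged from -0.16 to 0.43 with rATG at 10 µg/mL and 6 h and from -0.08 to 0.51 in rATG against hATG there.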

Other observations

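The following genes were chosen from those the naming rule gave, after their values were seen, and no explanation was tested for them. IL3RA, the interleukin 3 receptor of dendritic cells and basophils, rose with rATG at 10 µg/mL by 1.98 ± 0.42 at 24 h and 2.07 ± 0.42 at 6 h, and by 1.77 ± 0.42 and 2.24 ± 0.42 at 2.5 and 40 µg/mL. CD59, which shields cells from complement, rose with rATG at 10 µg/mL by 1.60 ± 0.21 at 24 h and 0.99 ± 0.21 at 6 h, and by 1.17 ± 0.21 at 40 µg/mL. At 2.5 µg/mL CD59 rose by 0.887 (adjusted p = 0.00346), a value for which no alternative was run. It was higher with rATG than with hATG at 10 µg/mL at both times (1.10 ± 0.21 and 1.05 ± 0.21) and at 40 µg/mL (0.93 ± 0.21). At 2.5 µg/mL that difference was 0.68 ± 0.21, and its call was lost in some alternatives. Of other complement regulators, CD55 fell with rATG at 2.5 µg/mL (-1.06 ± 0.22). CD46 was lower with rATG than with hATG after 6 h at 10, 2.5 and 40 µg/mL (-0.46 ± 0.09, -0.43 ± 0.09 and -0.49 ± 0.09), which was lost at each dose with the median of its probe sets (0.14 at 10 µg/mL, the opposite sign), at 10 and 2.5 µg/mL when only the groups compared were fitted, and at 2.5 µg/mL with median centring. SERPING1, the inhibitor of complement C1, rose after 6 h with rATG at 2.5 and 40 µg/mL (at least 2.01 and at least 1.82), and C5AR1, the receptor of C5a, fell (-1.60 ± 0.33 and -1.39 ± 0.33). In the Complement and Fc receptors list 2 of 15 measured genes rose and 0 fell with rATG at 24 h (2 and 0 adjusted over the list alone), and the list did not pass (camera, adjusted p = 0.306). After 6 h with rATG it did not pass either (adjusted p = 0.121, 0.891 and 0.618 at 10, 2.5 and 40 µg/mL). CD244, a receptor of natural killer and T cells, fell with rATG at 10 µg/mL at 24 h and 6 h and at 40 µg/mL (-1.79 ± 0.38, -1.84 ± 0.38 and -1.85 ± 0.38), and POU2AF1, a B cell co-activator, fell at 10 µg/mL and 6 h (-1.51 ± 0.33).

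In untreated cells the complement genes CFD and CFP (factor D and properdin) and CD59 were lower at 24 h than at 6 h (-1.67 ± 0.33, -1.54 ± 0.28 and -1.72 ± 0.21), as was FCER1A, a chain of the IgE receptor (-2.33 ± 0.34). The heat shock gene HSPH1 was lower (-1.72 ± 0.27), and so were the replication genes MCM4 and PCNA (-1.36 ± 0.22 and -0.97 ± 0.13). Of 25 measured genes of the Proliferation list, 0 rose, 6 fell and 19 did not pass (0 and 6 adjusted over the list alone). Its median was -0.47 (camera, adjusted p = 0.0434, and adjusted p = 0.635 with an estimated correlation). In the Immediate early and heat shock list 0 of 13 measured genes rose, 5 fell and 8 did not pass (0 and 5 adjusted over the list alone). The median was -0.28 (camera, adjusted p = 0.0328, and adjusted p = 0.405 with an estimated correlation).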
